A study of Rattus norvegicus with 6 samples.

How the data were processed

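Gene expression was measured in the renal cortex of male Sprague-Dawley rats with 1-colour (Cy3) Agilent oligonucleotide arrays, 1 array per animal. Per the labels, 3 rats received corn oil (vehicle) and 3 received the 4,4' isomer of thiobis(6-tert-butyl-m-cresol), written TBBC here, at 300 mg/kg/day, both for 4 weeks. Groups and replicate numbers were taken from the sample titles. The series' design text calls the replicates biological.

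The deposited scanner files hold spot intensity values that the authors obtained with Agilent Feature Extraction 10.7.1.1, per the file headers (10.7 per the submitters' processing notes). The processed intensity is background-subtracted and detrended within each array by that program and is not scaled between arrays. The deposited value table holds, for each probe, a linear ratio. Set against the scanner values, this ratio was the processed signal divided by a number within 0.3% of the array's 75th percentile, with no log and no centring of probes; the column medians were 0.111, 0.112 and 0.113 for vehicle 1 to 3, and 0.113, 0.107 and 0.114 for TBBC 1 to 3. The authors' statistical method is not given in the sources used here.

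Of 62976 spots, 1439 control spots were left out, leaving 61537 probes. The scanner files give a transcript accession per probe and no gene symbol. Accessions without versions were matched to a RefSeq gene table of assembly GRCr8, which named 28206 probes of 15645 genes; 33331 probes stayed unnamed. The file headers name another genome build, so no coordinates are given. Signals were divided by the array's 75th percentile over non-control probes and put on the log2 scale. Spots with an outlier flag (0 to 9 per array) were left out on that array, and no spot was saturated. A probe was tested when it lay well above background on every unflagged array of at least 1 group and had at least 2 unflagged arrays per group. This left 41992 probes. A gene was represented by its brightest tested probe and an unnamed probe stood for itself, giving 32956 transcripts, of which 12298 were named genes. A probe not well above background on any array of a group has only a bound there. Its fold is given as at least the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

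Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all transcripts tested and a threshold of 0.05. Errors of log2 fold changes are standard errors from that fit. The number of arrays limits the precision. In all, 37 gene lists for kidney cell types, other tissues and stress and metabolic responses were written from textbook knowledge. Each was tested with camera (preset inter-gene correlation 0.01, adjusted over the 37 lists). The genes named are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap and which were measured in both groups, those with only a bound, the 4 members of each list with the smallest p, and a fixed set of kidney genes. A list with no member past the threshold may have 1 example or only its counts. From the fixed set, Cyp1a1 and Cyp2b1 did not pass the filter on dim probes, and some genes of the set are not reported here. These 37 lists, the tests, this rule and the alternatives were fixed before the data were examined. Further lists for hypotheses (ribosomal proteins, cytosolic and mitochondrial aminoacyl-tRNA synthetases, selenoproteins, glucocorticoid-responsive genes, metallothioneins, tight junctions and the arms of the clock) were written after the group comparison had been seen.

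Alternatives were other scalings (quantile, median, 75th percentile over probes detected on all 6 arrays), normexp background correction with an offset of 50, the authors' value table, other filters on dim probes and flags, other ways of combining probes, eBayes with trend and robust, array weights, slide as a fixed term or random block (statmod 1.5.0), the slide that holds both groups alone, the replicate number as a block, each array left out in turn, and, for lists, camera with an estimated correlation and fry. The scanner files used here have no mean signal column, so normexp was run on the median signal. The procedure was tested on simulated data with the real vehicle means and, for both groups, each transcript's pooled spread, drawn independently. Of 50 transcripts changed per size, 22 were recovered at 2-fold, 40 at 4-fold, 47 at 8-fold and 49 at 16-fold. There were 8 false calls among the unchanged of 32956 transcripts. In simulated data with no change, 0 transcripts were called. As the real TBBC spread was larger for 74.3% of transcripts, these rates may not hold for the real arrays.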

Results

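The renal cortex of 3 vehicle-treated and 3 TBBC-treated rats was profiled to find which transcripts differ after 4 weeks of TBBC, a sulfur-bridged phenolic antioxidant, at 300 mg/kg/day. The replicates were biological, 1 array per animal. On each array 67.1% to 70.9% of the 61537 probes lay well above background, the lowest share being that of TBBC 2, and the 75th percentile of the processed signal ran from 861 in TBBC 2 to 1038 in vehicle 3. Pearson correlations across transcripts were 0.992 within the vehicle group, 0.983 to 0.985 within the TBBC group and 0.975 to 0.985 between groups. The first principal component held 45.4% of the variance and placed the vehicle arrays at -42, -40.2 and -48.2 and the TBBC arrays at 20.6, 72 and 37.8. The second component held 20.5% and set TBBC 3 apart, at -64 against 19.2 and 34.7 for TBBC 1 and 2. The vehicle arrays lay there at 4.8, -2.3 and 7.5. The median standard deviation of a transcript was 0.13 on the log2 scale among vehicle rats and 0.23 among TBBC rats. It was larger in the TBBC group for 74.3% of transcripts.

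Single genes of kidney injury, antioxidant defence and asparagine synthesis rose in the TBBC-treated cortex. Havcr1 (kidney injury molecule 1, shed by damaged proximal tubule cells) rose 89.3-fold, from -4.43 ± 0.29 to 2.05 ± 1.55, and Spp1 (osteopontin) rose 35.6-fold, from 2.55 ± 0.34 to 7.70 ± 0.41 (log2 relative to the array's 75th percentile, SD, n = 3). Havcr1 was highest in TBBC 2, at 3.83 against 1.33 in TBBC 1 and 0.99 in TBBC 3, and without TBBC 2 its log2 fold change was 5.59 in place of 6.48. Nqo1, a quinone reductase and a classical Nrf2 target, rose 23.0-fold, and Asns (asparagine synthetase) rose 13.0-fold. Among the genes that fell were Dio1, the deiodinase that activates thyroid hormone, with a log2 fold change of -2.46 ± 0.32 (SE), Col4a4, a collagen chain of the glomerular basement membrane, at -1.98 ± 0.15, and the clock genes Npas2 and Bmal1. Adjusted p-values (limma) were 0.0343 for Havcr1, 0.00434 for Spp1, 0.0140 for Nqo1, 0.00944 for Asns, 0.0449 for Dio1 and 0.0152 for Col4a4. With 1 array left out in turn, the calls of Nqo1, Asns and Col4a4 held in 3 of 6 fits and those of Havcr1 and Dio1 in 2.

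In all, 175 of 32956 transcripts passed the threshold, 84 higher and 91 lower in TBBC, and 148 of them differed at least 2-fold. Named genes made up 83 of the 175, with 40 higher and 43 lower, and 92 were probes without a name here. At an unadjusted p under 0.05 there were 6577 transcripts. The groups did not overlap in 28.3% of transcripts, where the average over all splits of the 6 arrays into 3 and 3 is 10%. Transcripts may vary together, so a single split can lie above that average without an effect of TBBC. Another 497 named genes differed at least 2-fold without passing. Other probes of the called genes had the same sign in 61 cases and the opposite sign in 2, both of Rgs11.

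The count of calls depended on which arrays were left out and on how slide entered the fit. Without vehicle 1, 2 or 3 the count was 10, 6 or 14, and without TBBC 1, 2 or 3 it was 254, 58 or 274. Limma assumes 1 spread for both groups. Without a vehicle array that spread leans more on the TBBC rats, whose median SD was larger, and without a TBBC array less. How far this explains the counts was not tested. Of the 43 genes named here that passed, Spp1 and Egr1 did so whichever array was left out. The calls of Fmo1, Slc22a25, Dbp, Trim63, Rarres1, Peli2, Fabp12, Lcn9 and Olr1096 were lost with any 1 array left out. They were also lost with slide as a fixed term (adjusted p from 0.167 to 0.211), as a random block (0.0539 to 0.0677) and within the shared slide (0.0808 to 0.153). The vehicle arrays and TBBC 1 shared slide 1 and scan 1, while TBBC 2 and TBBC 3 were on slide 2 and scan 2. With slide as a fixed term 48 transcripts were called (43 higher, 5 lower), 28 of them among the 175. Slide as a random block left 122 (62 higher, 60 lower), and the shared slide alone, with 3 vehicle arrays and 1 TBBC array, gave 307 (263 higher, 44 lower). In that last fit the spread comes from the vehicle arrays, and the lone TBBC array is assumed to vary like them. With slide as a fixed term the difference between groups also rests on TBBC 1 alone, as slide 2 holds no vehicle array. Calls lost under either fit can therefore follow from losing TBBC 2 and TBBC 3 from the comparison. They do not show a slide effect. Under the fixed-term, random-block and shared-slide fits all 175 transcripts had the same direction as before. TBBC 1 helped to choose the 175, so this shared direction is no independent evidence against a slide effect. Within the shared slide the log2 fold changes were 5.76 for Havcr1, -1.83 for Col4a4 and -1.16 for Bmal1. Of the 43 named calls, 33 were lost with slide as a fixed term, 18 with slide as a random block and 24 within the shared slide. With slide as a fixed term the limma adjusted p was 0.175 for Havcr1, 0.167 for Dio1, 0.101 for Col4a4, 0.195 for Npas2 and 0.120 for Bmal1. Dio1 and Npas2 lost their calls with the random block as well (0.0601 and 0.0578) but passed within the shared slide (0.0306 and 0.0224, with log2 fold changes of -1.85 and -1.78). Col4a4 and Bmal1 lost theirs within the shared slide (0.0599 and 0.0777). Over all alternatives the adjusted p ran from 0.0101 to 0.175 for Havcr1, 0.0180 to 0.197 for Dio1, 0.00484 to 0.116 for Col4a4, 0.0189 to 0.195 for Npas2 and 0.00853 to 0.154 for Bmal1.

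**Figure D1:**
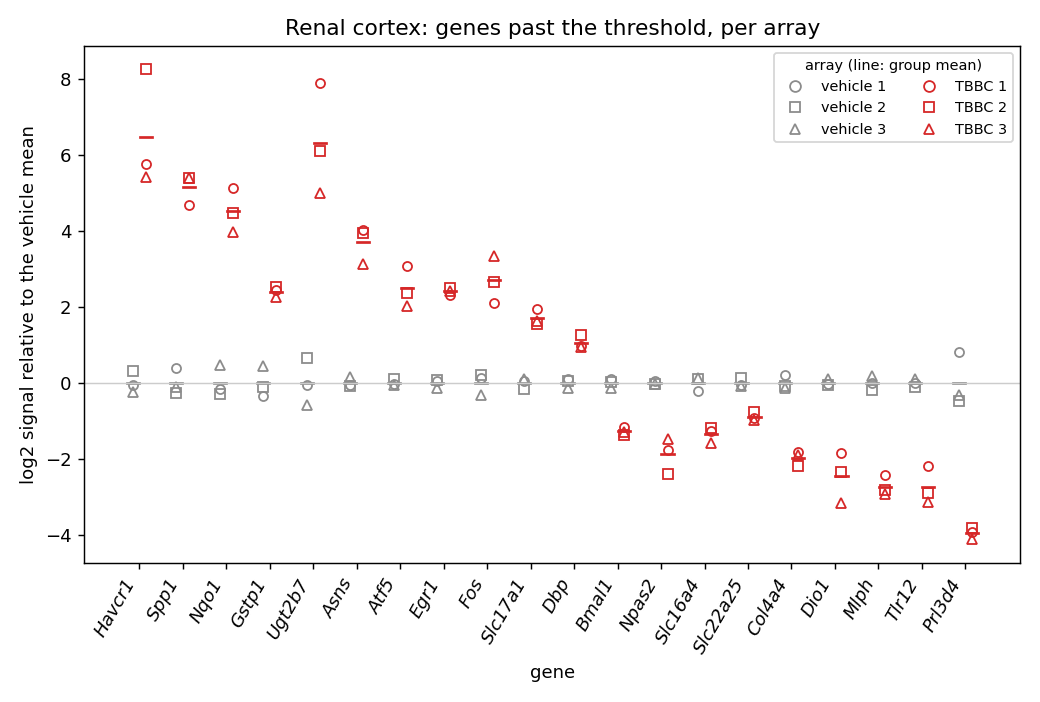
Each symbol is 1 array's log2 signal of a gene (x axis) minus the mean of the 3 vehicle arrays (y axis), grey for vehicle and red for TBBC, with a line at each group mean. Havcr1 has the widest spread among the TBBC arrays shown (SD 1.55), and Egr1 has an SD of 0.10.

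Of 41 antioxidant genes linked to Nrf2, 6 rose, 0 fell and 35 did not pass; adjusted over the list alone 18 rose. The median log2 fold change was 0.60 (camera, adjusted p = 1.54e-14; adjusted p = 0.385 with an estimated correlation), and the list medians of TBBC 1, 2 and 3 were 0.60, 0.95 and 0.38. Besides Nqo1, the members that rose included the glutathione transferase Gstp1 (log2 fold change 2.41 ± 0.22, adjusted p = 0.0181 in limma), Mgst1 (1.06 ± 0.11, adjusted p = 0.0293) and the efflux pump Abcc4 (2.12 ± 0.24, adjusted p = 0.0343). Hmox1, which encodes heme oxygenase 1, was at 2.33 ± 0.84 and Gclc, the catalytic subunit of glutamate-cysteine ligase, at -1.46 ± 0.83, and neither passed. Ugt2b7, a glucuronosyltransferase outside the lists, rose with a log2 fold change of 6.33 ± 0.74 (adjusted p = 0.0346). Its rise was 80.6-fold with all arrays, 46.9-fold without TBBC 1 and 128-fold without TBBC 3. Calls held in 3 of 6 fits with 1 array left out for Gstp1, in 2 for Mgst1 and Ugt2b7 and in 1 for Abcc4. Of 32 phase I and II xenobiotic enzymes, 1 rose (Nqo1, which is on both lists), 1 fell (Fmo1, a flavin monooxygenase, 2.00-fold lower, adjusted p = 0.0472) and 30 did not pass; adjusted over the list alone 6 rose and 8 fell. The list median was -0.33 (camera, adjusted p = 0.268). Sult1c2 was at -2.96 ± 0.43 and did not pass. Cyp3a9 was not well above background in any vehicle rat and at least 1.34-fold higher in TBBC, without passing.

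Tubular injury markers had a median log2 fold change of 0.88 (camera, adjusted p = 1.24e-10; adjusted p = 0.312 with an estimated correlation). Of 33 members, 2 rose (Havcr1 and Spp1), 0 fell and 31 did not pass; adjusted over the list alone 16 rose and 1 fell. Other members were Lcn2, a secreted lipocalin, at 2.92 ± 0.74, Timp1, a metalloproteinase inhibitor, at 2.08 ± 0.36, Clu (clusterin) at 1.57 ± 0.68, Slc34a2 at 2.46 ± 0.39 and Cd24 at 0.71 ± 0.11. Clu was not above the vehicle range in TBBC 1, whose value was 3.85 against a vehicle mean of 3.94 ± 0.16 (SD, n = 3).

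The unfolded protein and integrated stress response list had a median of 0.80 (camera, adjusted p = 1.24e-10; adjusted p = 0.411 with an estimated correlation). Of 40 members, 2 rose, Asns and the transcription factor Atf5 (2.49 ± 0.27, adjusted p = 0.0302 in limma), and 38 did not pass; adjusted over the list alone 11 rose. Atf3 was at 2.98 ± 0.55 and the chaperone Dnajc3 at 1.23 ± 0.26. Outside this list, Eif4ebp1, a repressor of cap-dependent translation, rose by 2.29 ± 0.28 (adjusted p = 0.0388 in limma). Calls held in 2 of 6 fits with 1 array left out for Atf5 and in 1 for Eif4ebp1. Heat shock proteins had a median of 0.23 (camera, adjusted p = 0.0192; adjusted p = 0.566 with an estimated correlation; adjusted p = 0.0621 without TBBC 2, range over the camera alternatives 0.00316 to 0.0621), with 0 of 14 members past the threshold, 2 higher adjusted over the list alone, and Hspa1a at 1.30 ± 0.18.

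Immediate early genes had a median of 0.54 (camera, adjusted p = 1.44e-06; adjusted p = 0.524 with an estimated correlation). Of 24 members 3 rose, namely the transcription factors Egr1 (2.41 ± 0.12, adjusted p = 0.00434 in limma) and Fos (2.71 ± 0.33, adjusted p = 0.0384) and the antiproliferative gene Btg2 (1.01 ± 0.13, adjusted p = 0.0457); adjusted over the list alone 10 rose and 1 fell. With 1 array left out, the call of Fos held in 2 of 6 fits and that of Btg2 in 1. Both were lost with slide as a random block (limma, adjusted p = 0.0515 and 0.0601). Fosl1 was not well above background in any vehicle rat and at least 27.7-fold higher in TBBC, without passing. The p53 targets had a median of 0.25 (camera, adjusted p = 0.00309; adjusted p = 0.457 with an estimated correlation), with 1 of 23 past the threshold (Btg2) and 4 higher and 1 lower adjusted over the list alone; Fas was at 1.29 ± 0.25 and Cdkn1a, the p21 cell cycle inhibitor, at 0.03 ± 0.10. Apoptosis genes had a median of 0.16 (camera, adjusted p = 0.00132; adjusted p = 0.304 with an estimated correlation), with 0 of 25 past the threshold, 4 higher adjusted over the list alone, and Ripk3 at 1.02 ± 0.17. Inflammation, chemokine and complement genes had a median of 0.53 (camera, adjusted p = 4.5e-06; adjusted p = 0.385 with an estimated correlation), with 0 of 31 past the threshold, 11 higher adjusted over the list alone, and the chemokines Ccl2 at 1.39 ± 0.27 and Cxcl1 at 2.44 ± 0.52. The list of cholesterol synthesis genes and SREBP2 targets had a median of 0.34 (camera, adjusted p = 5.42e-05, and 0.524 with an estimated correlation). In it 0 of 30 passed the threshold and 1 was higher adjusted over the list alone. Elovl6 was at 1.32 ± 0.22 and Sqle at 1.13 ± 0.26.

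Transporters and brush border genes of the proximal tubule, the segment that reabsorbs most filtered solute, had a median log2 fold change of -0.34, with list medians of -0.34, -0.35 and -0.36 in TBBC 1, 2 and 3 (camera, adjusted p = 1.38e-05; adjusted p = 0.169 with an estimated correlation). Of 50 members 1 rose, 2 fell and 47 did not pass. Adjusted over the list alone 2 rose and 14 fell. Whatever their p, 7 members were at least 2-fold lower and 2 at least 2-fold higher. The lowest member, at -4.18, did not pass, and the male-biased list had the same lowest value. Slc16a4 (-1.35 ± 0.16, adjusted p = 0.0346 in limma) and Slc22a25 (-0.89 ± 0.12, adjusted p = 0.0441) fell, while Slc17a1, a sodium-phosphate and organic anion transporter, rose (1.70 ± 0.15, adjusted p = 0.0181). Calls held in 3 of 6 fits with 1 array left out for Slc17a1, in 1 for Slc16a4 and in 0 for Slc22a25. With slide as a fixed term the Slc16a4 call was lost (limma, adjusted p = 0.171). The abundant proximal genes Slc34a1 (-0.15 ± 0.14), Slc22a6 (-0.31 ± 0.17) and Lrp2 (-0.37 ± 0.10) did not pass. Proximal amino acid, gluconeogenic and organic acid metabolism had a median of -0.23 (camera, adjusted p = 0.000498; adjusted p = 0.312 with an estimated correlation), with 0 of 39 past the threshold, 5 lower adjusted over the list alone, and Hao2 at -1.16 ± 0.23. Oxidative phosphorylation subunits had a median of -0.21 (camera, adjusted p = 6.31e-08; adjusted p = 0.566 with an estimated correlation). None of 50 passed, 49 were below and 1 above the vehicle mean, and Cycs (cytochrome c) was at -0.71 ± 0.14.

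Thick ascending limb markers had a median of -0.26 (camera, adjusted p = 0.0113; adjusted p = 0.572 with an estimated correlation), with 0 of 18 past the threshold and 2 lower adjusted over the list alone. Egf was at -1.33 ± 0.28 and Umod (uromodulin) at -0.91 ± 0.33. Intercalated cell markers had a median of -0.25 (camera, adjusted p = 0.0113; adjusted p = 0.572 with an estimated correlation), with 0 of 19 past the threshold and Car2 at -0.58 ± 0.15. The calls of both lists ended with slide as a fixed term and within the shared slide. In these fits the group difference rests on TBBC 1, which within the shared slide is assumed to vary like the vehicle arrays. The call of the intercalated list also ended without vehicle 1 (camera, adjusted p = 0.0862) and without TBBC 3 (adjusted p = 0.0749). Over the camera alternatives the adjusted p ran from 0.00246 to 0.245 for the thick ascending limb list and from 0.000184 to 0.139 for the intercalated list. Camera called 14 of 37 lists, 9 up and 5 down, and 0 with an estimated correlation. Among the called lists that correlation ran from -0.017 (proximal transporters) to 0.395 (oxidative phosphorylation). For the proximal transporters and for apoptosis (-0.011) it lay below the preset 0.01. A higher correlation of members therefore does not explain the loss of these calls. For the other lists its part was not tested. With slide as a fixed term and as a random block camera called 13 and 14 lists.

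**Figure D2:**
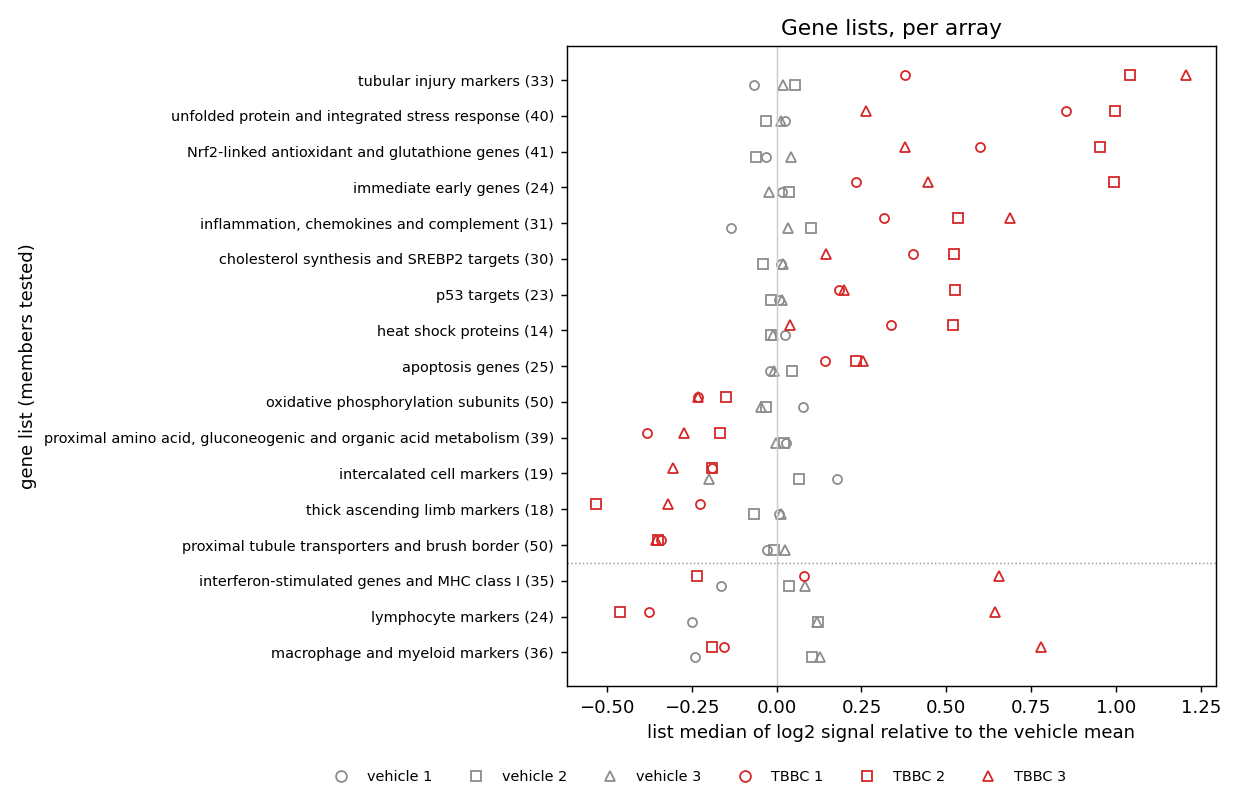
Each symbol is 1 array's median over the tested members of a gene list (y axis, members tested in brackets) of the log2 signal minus the vehicle mean (x axis), grey for vehicle and red for TBBC. The 14 called lists are above the dotted line and 3 leukocyte-related lists below it, where TBBC 3 is at 0.64 to 0.78 and the other TBBC arrays are at -0.46 to 0.08.

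Markers of leukocytes stood apart in TBBC 3, and whether camera called their lists depended on the arrays used. Macrophage and myeloid markers (0 of 36 past the threshold, median 0.13, camera adjusted p = 0.269) had array medians of -0.15, -0.19 and 0.78 in TBBC 1, 2 and 3, against -0.24, 0.10 and 0.13 in the vehicle rats. Lymphocyte markers (0 of 24, median -0.05, adjusted p = 0.870) had array medians of -0.38, -0.46 and 0.64, and interferon-stimulated and MHC class I genes (0 of 35, median 0.16, adjusted p = 0.135) had 0.08, -0.23 and 0.66. Adjusted over the list alone, 2 interferon-stimulated genes rose and 1 fell. The myeloid list was called higher without TBBC 1 (adjusted p = 0.0440) or TBBC 2 (0.0186), with a range over the camera alternatives of 0.0186 to 0.830. The interferon list was called higher without vehicle 3 (0.0450) or TBBC 2 (0.00197), with a range of 0.00197 to 0.890. The lymphocyte list was called lower without TBBC 3 (0.000478) and within the shared slide (0.00776), with a range of 0.000478 to 0.985. Inflammation genes, of which 0 of 31 passed and whose camera call did not hold with an estimated correlation (adjusted p = 0.385), had array medians of 0.32, 0.54 and 0.69 in TBBC 1, 2 and 3.

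The other lists gave no camera call on all 6 arrays, with adjusted p-values from 0.0619 (male-biased genes) to 0.870. The medians were -0.29 for proximal S3 markers (0 of 15 past the threshold), -0.23 for distal convoluted and connecting tubule (0 of 18), -0.17 for principal cells (0 of 18), -0.22 for podocytes (0 of 21), -0.27 for endothelium (0 of 19), 0.09 for fibroblasts and matrix (0 of 34), -0.05 for smooth muscle (0 of 11) and -0.28 for the cell cycle (0 of 45). They were -0.14 for fatty acid oxidation (0 of 48), -0.01 for glycolysis (0 of 22), -0.06 for vitamin D, calcium and phosphate handling (0 of 23), -0.10 for blood pressure genes (0 of 20), -0.38 for male-biased genes (0 of 16), -0.09 for adipocytes (0 of 9), -0.10 for adrenal cortex (0 of 7), -0.32 for hepatocyte proteins (0 of 17) and -0.20 for blood (0 of 10). For hepatocyte proteins vehicle 1 stood apart, with array medians of 0.77, -0.37 and -0.17 in the vehicle rats and -0.36, -0.56 and -0.61 in the TBBC rats. For vitamin D, calcium and phosphate handling the mean was 0.15, of the opposite sign to the median. Adjusted over the list alone, 1 member rose and 1 fell among S3 markers, 1 fell among distal tubule markers, 2 rose among matrix genes, and 3 rose and 2 fell in fatty acid oxidation. In the same way 1 rose in glycolysis, 1 rose and 3 fell in vitamin D handling, 2 rose and 1 fell among blood pressure genes, and 3 male-biased genes fell. Several of these lists were called, in the direction they had on all 6 arrays, when an array was left out. Without TBBC 2 these were S3 markers (adjusted p = 0.0462), distal tubule (0.0462), podocytes (0.0290), endothelium (0.0330), matrix (0.00255), fatty acid oxidation (0.00255) and male-biased genes (0.0182). Without TBBC 1 they were S3 markers (0.0440), podocytes (0.0456) and matrix (0.0456), and without TBBC 3 iron and heme (0.0449). Without vehicle 1 they were endothelium (0.0446), fatty acid oxidation (0.0365), iron and heme (0.0122) and male-biased genes (0.0347). Without vehicle 2 they were hepatocyte proteins (0.00739) and male-biased genes (0.0326), and without vehicle 3 podocytes (0.0450) and male-biased genes (0.0245). Fatty acid oxidation was also called with slide as a fixed term (0.0254) and within the shared slide (0.0199). Normexp with quantile normalization called S3 markers (0.0406), podocytes (0.0379), endothelium (0.0302), fatty acid oxidation (0.0277), iron and heme (0.0406) and male-biased genes (0.0295). Quantile normalization called fatty acid oxidation (0.0415) and male-biased genes (0.0332), and the mean over probes called iron and heme (0.0454). Over the camera alternatives the highest adjusted p of these lists lay between 0.284 (iron and heme) and 0.938 (matrix). Iron and heme genes had a median of 0.12, with 1 of 26 past the threshold, the transferrin receptor Tfrc (1.28 ± 0.17, adjusted p = 0.0462 in limma). The Tfrc call held in 1 of 6 fits with 1 array left out. It was lost with slide as a random block (limma, adjusted p = 0.0578). Abcc2 was at 3.53 ± 0.57, Cyp27b1, which makes active vitamin D, at -1.47 ± 0.27, Cyp24a1 at 0.88 ± 0.82, Kl (klotho) at -0.64 ± 0.19, Slc12a3 at 0.26 ± 0.14, Calb1 at -0.11 ± 0.28, Aqp2 at -0.38 ± 0.18 and Mki67 at -0.34 ± 0.28, and none of these passed.

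Among 16 circadian clock genes, 2 fell, 1 rose and 13 did not pass; adjusted over the list alone 2 rose and 2 fell. Bmal1 (-1.27 ± 0.12, adjusted p = 0.0188 in limma) and Npas2 (-1.89 ± 0.24, adjusted p = 0.0406), which encode partners in one arm of the clock, fell, and Dbp, an output gene of the opposite phase, rose (1.05 ± 0.13, adjusted p = 0.0423). The Dbp call was lost with any 1 array left out and under each slide fit, where its adjusted p was 0.188, 0.0581 and 0.0953. The list median was -0.04 while the camera direction was up (adjusted p = 0.870), as members went both ways. Nr1d2 was at 0.92 ± 0.14 without passing. The calls of Bmal1 and Npas2 each held in 2 of 6 fits with 1 array left out.

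Some named genes that did not pass with all 6 arrays passed in limma with 1 left out. Without TBBC 1 these were Lcn2, Clu, Timp1, Cxcl1, Dnajc3, Egf and Hao2 (adjusted p from 0.0116 to 0.0457), with log2 fold changes of 3.83 for Lcn2 and 2.39 for Clu. Without TBBC 3 they were Abcc2, Atf3, Fosl1 and Sult1c2 (adjusted p from 0.00905 to 0.0393), with Abcc2 at 4.21, and without vehicle 3 Slc34a2 passed (0.0283). Without TBBC 2, Hmox1 was at 1.36 and Cyp24a1 at -0.08, and neither passed. In fits without a TBBC array the assumed common spread leans more on the vehicle rats, whose median SD was smaller. Passing there is weaker evidence than with all 6 arrays.

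Outside the lists, Cybrd1, a duodenal-type ferric reductase, rose by 2.25 ± 0.20 (adjusted p = 0.0181 in limma) and Sfnl1 by 2.14 ± 0.27 (adjusted p = 0.0417). Their calls held in 3 and 1 of 6 fits with 1 array left out. The Sfnl1 call was also lost with slide as a random block (limma, adjusted p = 0.0561). Other genes that fell, among those measured in both groups, were Prl3d4 at -3.96 ± 0.35 (adjusted p = 0.0181), the toll-like receptor gene Tlr12 at -2.75 ± 0.25 (adjusted p = 0.0181), Mlph (melanophilin) at -2.74 ± 0.17 (adjusted p = 0.00876), Btg1b at -2.65 ± 0.32 and Tmem86a at -2.36 ± 0.15 (adjusted p = 0.00876). Over all alternatives the log2 fold change of Prl3d4 was as small as -2.76. With 1 array left out, calls held in 3 of 6 fits for Prl3d4 and Mlph, 2 for Tlr12, 1 for Btg1b and 4 for Tmem86a. Dnajc5b was lower (limma, adjusted p = 0.0471) but well above background in 1 of 3 TBBC rats, so no size is given. Trim63 (-1.94 ± 0.25, adjusted p = 0.0423), Rarres1 (-1.93 ± 0.24, adjusted p = 0.0388) and Peli2 (-1.77 ± 0.24, adjusted p = 0.0472) fell with calls that did not hold with any 1 array left out. For Peli2 the mean over its probes gave -0.67. In the TBBC group Cngb3 was not well above background and at least 16.1-fold lower (adjusted p = 0.00876), and so were Ccn6 (at least 9.07-fold), Usp26 (5.06-fold), Lcn9 (3.53-fold), Fabp12 (1.93-fold), Rdh7 (1.89-fold) and Olr1096 (1.42-fold). Of 6 fits with 1 array left out, the call held in 5 for Cngb3, in 1 each for Ccn6, Usp26 and Rdh7, and in 0 for Lcn9, Fabp12 and Olr1096. Under normexp, whose offset shrinks the folds of dim probes by construction, the calls of Lcn9, Fabp12, Rdh7 and Olr1096 were lost, with log2 fold changes as small as -0.74, -0.34, -0.29 and -0.05. The bounds therefore hold only for the processed signal. In the vehicle group Reg3b, a secreted lectin of injured epithelia, was not well above background and at least 9.26-fold higher in TBBC (adjusted p = 0.0164), and the protease gene Prss22 at least 4.64-fold higher (adjusted p = 0.0181), with calls that held in 3 and 2 of the 6 fits.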

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

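The 3 vehicle and 3 TBBC arrays gave 175 called transcripts (84 higher, 91 lower, 148 at least 2-fold) and 14 called lists, and no named gene or list reversed its direction with a call under any alternative. All alternatives reported here were planned, so none of these tests was chosen after the result was seen. Leaving out 1 array at a time gave 6 to 274 transcripts (4 to 184 higher, 2 to 134 lower, 6 to 239 at least 2-fold) and 15 to 22 lists. Normexp with quantile normalization called 642 (301 higher, 341 lower), normexp with the 75th percentile 761 (424 higher, 337 lower, 223 at least 2-fold), and eBayes with trend and robust 1087 (621 higher, 466 lower, 354 at least 2-fold). With no filter on dim probes the count was 52 (27 higher, 25 lower, 52 at least 2-fold) of 48976 tested, and with every probe counted separately 333 (158 higher, 175 lower, 253 at least 2-fold) of 41992. Groups that do not overlap were found for 9328 transcripts (4319 higher, 5009 lower, 976 at least 2-fold). The average over all splits of the arrays is 10%, which a single split can exceed without an effect when transcripts vary together. Slide as a fixed term left 48 (43 higher, 5 lower, 48 at least 2-fold), the shared slide alone gave 307 (263 higher, 44 lower, 307 at least 2-fold; its 1 TBBC array is assumed to vary like the vehicle arrays), and slide as a random block left 60 lower calls. The cause of these changes was not tested, except that settings with fewer arrays or more transcripts tested differ in that by construction. Leaving out a vehicle or a TBBC array also changes how much the wider spread of the TBBC rats counts in the fit. With slide as a fixed term, as within the shared slide, the group difference rests on TBBC 1 alone. With the replicate number as a block, limma called 0 transcripts in total, 0 higher, 0 lower and 0 at least 2-fold, with 5366 at an unadjusted p under 0.05. Deviations of same-numbered arrays correlated at -0.095, 0.033 and -0.074, and no vehicle array correlated best with the TBBC array of its own number. Other pairs ran from -0.126 to 0.212. These values gave no sign of a pairing by number, but so few arrays cannot exclude one. Lists called fell to 0 with an estimated correlation and to 5 with fry. Fry tests whether members move on balance 1 way. It kept the Nrf2, tubular injury, proximal transporter, proximal metabolism and apoptosis lists. The estimated correlation of the proximal transporter and apoptosis lists lay below the preset value. The fall to 0 therefore does not by itself show that members vary together. Camera called 16 lists with quantile normalization, 20 with normexp and quantile normalization, 15 with the mean over probes and 16 with the replicate block, which added podocytes and male-biased genes (adjusted p = 0.0488 each). The median log2 fold change of all transcripts stayed between -0.03 and 0.02 over the scalings. Of the named genes' calls and non-calls, 2858 kept their side and direction, 169 weakened and 118 strengthened over the other alternatives. Leaving out arrays, 918 kept them, 179 weakened and 19 strengthened. Only 43 of these 186 genes were called with all 6 arrays, so most results that were kept are non-calls. A weakened result is a lost call. Of the 43 calls, 39, 41 or 38 were lost without vehicle 1, 2 or 3. Without TBBC 1, 2 or 3, 17, 29 or 15 were lost. The authors' value table gave 175 calls, the same transcripts. Probes near background limit what can be said of dim genes: 26 of the 175 calls have only a bound in 1 group.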

Other observations

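Apart from the count of splits, the tests here were chosen after the group comparison was seen. Those of the slide, cell type shares, the clock phase, the scaling of the proximal list, the selenoproteins without Nrf2 members and the technical explanations for ribosomal protein genes were chosen after the result was seen that they measure. For the glucocorticoid list, the value of 1 member (Sgk1) had been seen. Ribosomal protein genes were listed after the value of 1 member (Rpl19) had been seen, and lay higher in TBBC in 56 of 56 members tested. Their median log2 fold change was 0.36, with a range of 0.06 to 0.95, and the array means relative to the median of all transcripts were 0.42, 0.40 and 0.36 in TBBC 1, 2 and 3 against -0.04, 0.03 and 0.01 in the vehicle rats. The difference was 0.39 (95% interval 0.32 to 0.47 from a linear model over the 6 arrays), and the groups did not overlap for 55 of the 56. By itself 1 member passed the threshold over all transcripts, Rpl19 (0.95 ± 0.12 SE, limma adjusted p = 0.0388), which was chosen after its value was seen. Metallothioneins and metal response genes differed by 0.33 (95% interval 0.05 to 0.61, 7 genes), tight junction and adherens genes by 0.08 (-0.01 to 0.17, 21 genes) and mitochondrial aminoacyl-tRNA synthetases by 0.08 (-0.11 to 0.27, 14 genes).

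For the ribosomal protein genes, a shift of bright probes in general is argued against: the highest median among 1000 lists of other named genes matched on mean signal was 0.0608. Scaling is argued against as well, since the list median lay at least 0.28 above the median of all transcripts under the 3 scalings that are not 1 factor per array (quantile normalization and both normexp settings). The other scalings move all transcripts alike. Probes of these genes may also bind transcripts of their many processed pseudogenes, and no RNA quality value was analysed, so these stay open together with an effect of TBBC.

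For the 175 transcripts that differed, 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05; the real split was the 1 split with as many calls, and the highest of the other splits gave 0. For slide and scan day, transcripts were called without TBBC 1, among those measured on all 6 arrays, and then looked up in TBBC 1, which shares its slide with the vehicle arrays. Of 263 called, 94.7% lay on the same side of the vehicle mean in TBBC 1, with a median relative size of 0.668. In simulations of all 6 arrays with TBBC 1 unchanged, this share had a median of 55.3% and was at most 85.7%. The simulations drew each transcript independently and called a median of 40.5 transcripts. They are therefore no fair yardstick for 263 transcripts that may vary together, and no conclusion is drawn from them. As only 1 TBBC array was on the shared slide, slide and treatment cannot be told apart for TBBC 2 and TBBC 3.

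For the lower proximal tubule transporters, scaling is argued against: under the 3 scalings that are not 1 factor per array, the list median lay between -0.42 and -0.35 relative to the median of all transcripts. A smaller share of proximal tubule RNA would raise the markers of the other kidney cell types; 111 such markers differed by -0.17 (95% interval -0.36 to 0.03). More medulla in the TBBC samples would raise thick ascending limb and principal cell markers, which differed by -0.19 (-0.40 to 0.02). Both intervals reach just above 0, so neither is excluded, and an effect of TBBC on these genes stays open as well.

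For the clock genes, a different phase at sampling may be involved. Over the members other than Bmal1, Npas2 and Dbp, genes of the opposite phase minus genes peaking with Bmal1 differed by 0.60 (95% interval -0.08 to 1.29), which does not decide it. Glucocorticoid-responsive genes differed by 0.00304 (95% interval -0.52 to 0.53), with 6 of 12 members higher, which does not decide it either. This mean near 0 does not show that the members were unchanged. They ran from -1.02 (Errfi1) to 1.08 (Zbtb16), and none passed. The members with the smallest p, Klf9 (-0.67), Fam107a (-0.84), Errfi1 and Pdk4 (-0.53), were lower.

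With Asns and Atf5, and with Pck2 and Mthfd1l, both picked after their values were seen, the cytosolic aminoacyl-tRNA synthetase genes were hypothesised to rise. All 20 lay above the vehicle mean, and relative to the median of all transcripts they differed by 0.45 on average (95% interval -0.25 to 1.14), but the array means were 0.49, 0.86 and -0.01 in TBBC 1, 2 and 3, so the question stays open. Because Dio1 and Selenop (picked after its value was seen) both encode selenoproteins, a fall of the class was tested. The 19 other members differed by 0.22 (95% interval -0.04 to 0.49), a value carried by Gpx2 (2.11) and Txnrd1 (1.33), which are also on the Nrf2 list. Without the members on that list, 16 genes differed by 0.03 (-0.18 to 0.25), with 9 above and 7 below the vehicle mean, among them Txnrd2 at -0.62 and Gpx3 at -0.54. This argues against a fall of the whole class by 0.3 or more, while a fall of single members or a smaller one stays open.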
